A study of Homo sapiens with 12 samples.

How the data were processed

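Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on T follicular helper (Tfh) cells, the CD4 T cells that help B cells in germinal centres. The cells were sorted from human tonsil as CXCR5-high and PD1-high memory CD4 T cells that lacked the B cell marker CD19. The targets were BCL6, a transcriptional repressor that directs Tfh differentiation, and 3 histone marks. H3K4me3 marks mainly promoters, H3K4me1 marks mainly enhancers, and H3K27ac marks active promoters and enhancers. The series lists 12 libraries, namely 2 per target and 4 input chromatin libraries. Peak lists were used here for 7 files, and the input libraries were not analysed here.

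Each deposited file is a list of called peaks with chromosome, start and end, and its values carry no other unit than a position in base pairs. Per the file headers, the BCL6 list holds the peaks that overlapped between BCL6 replicates 1 and 2, so both BCL6 replicates are represented by 1 joint list. Per the file headers, each histone list holds the peaks of 1 replicate. Whether the joint BCL6 list keeps the extent of replicate 1, of replicate 2 or of their shared part is not given in the sources used here. The genome build is hg18, per the file headers of the histone lists and per the submitters' processing notes. The aligner, the peak caller and its threshold are not given in the sources used here. Per the labels' descriptions, 1 input library matches each histone replicate number and 1 matches each BCL6 replicate. The deposited lists hold no score, height, fold or p-value per peak, so the read depth behind each peak is unknown and the precision of each call cannot be stated. The labels do not say whether replicates came from separate donors. No peak was matched to a gene, because the only gene table used here is on another build and coordinates were not converted. The gene lists fixed at the outset were therefore not tested.

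The smallest width with both ends counted was 100 bp in every list, so ends were taken as inclusive, and positions are printed as in the files. A histone region means the part of a peak called in both replicates. Any 2 intervals overlapped when they shared at least 1 bp. Each BCL6 peak was assigned to 1 of 5 classes. Promoter-type peaks overlapped H3K4me3, active enhancer-type peaks overlapped H3K4me1 and H3K27ac without H3K4me3, and unacetylated enhancer-type peaks overlapped H3K4me1 alone. The remaining peaks overlapped H3K27ac alone or were unmarked. Unacetylated means that no H3K27ac region of both replicates overlapped. These names describe combinations of marks and no annotated promoter or enhancer.

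Overlap was compared with chance by 1000 circular shifts of the peak list within each chromosome, between the first start and the last end of any list, which keeps peak widths and spacing. The empirical p-value, with both directions counted, cannot fall below 0.002 with 1000 shifts. Shares carry exact Clopper-Pearson 95% binomial intervals, which treat peaks as independent and cover counting error only. Peak widths stood in for the peak scores that the design had named, and medians were compared by permutation tests in both directions with 100000 resamples, or 10000 in alternatives. Occupancy of H3K4me1 regions was compared by Fisher's exact test and by a Mantel-Haenszel odds ratio over 5 width bins, set against the same odds ratio after 1000 shifts of the BCL6 list. Adjusted p-values follow Benjamini and Hochberg within the 3 marks, the 5 classes or the 6 pairs of classes. Profiles around BCL6 midpoints were computed every 100 bp out to 5 kb, with intervals from 1000 bootstrap draws of peaks. The bootstrap draws and the permutations of widths treat peaks as independent and do not measure variation between replicates. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

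The overlap test was tested on simulated data. It found 9 of 9 planted overlaps among 8523 simulated peaks with an error of at most 0.20 percentage points, and it called 10 of 120 tests of randomly placed lists. Planted odds ratios of 1, 2 and 4 over 69490 regions came back as 0.965, 2.05 and 4.10. The simulated groups were assigned without regard to region width, so this did not test the correction for width. The width test called 39 of 40 planted differences of 60 bp and 2 of 40 splits without a difference.

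The groups, tests, classes and alternatives were set before the data were examined, apart from the use of width in place of a score, the profiles, the local shifts, the 2 kb distance limit and the subsets of the widest peaks. Also added later were the comparison of H3K27ac at BCL6 peaks on and off H3K4me3, and the shares of H3K27ac regions that lay on the other marks. Alternatives used the union of both replicates, each replicate alone, overlap of the midpoint or of 50% of the peak, BCL6 peaks extended by 1 kb, random placement, autosomes only, local shifts of 20 to 500 kb, the widest 50% of each list, H3K4me1 regions over 2 kb from H3K4me3, and the mean of log2 width. Alternatives for H3K4me1 occupancy and for the histone lists used 200 shifts, with a smallest p of 0.01. Because the labels tie 1 input to each histone replicate number, same-numbered histone libraries were treated as one experiment. Base overlap (Jaccard index) between different marks averaged 0.168 for same-numbered and 0.168 for differently numbered libraries (6 pairs each). The regions named in the text were drawn from the 10 widest BCL6 peaks, the 5 widest of each class, and the 5 widest H3K27ac and H3K4me3 regions. The rule had named peaks by score, and width replaced it. Named regions were restricted to autosomes, a limit added later to keep sex chromosomes out of the text.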

Results

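The data comprised 7 peak lists from human tonsil Tfh cells. The joint BCL6 list held 8523 peaks with a median width of 309 bp (interquartile range 194 to 503 bp) and covered 3.32 Mb. H3K4me1 was called in 90320 peaks covering 57.8 Mb in replicate 1 and in 74750 peaks covering 40.5 Mb in replicate 2. H3K4me3 was called in 25625 peaks (22.1 Mb) and 27950 peaks (26.4 Mb), and H3K27ac in 26869 peaks (16.4 Mb) and 19962 peaks (9.64 Mb). The number of reads behind each list is unknown.

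The replicate lists of each histone mark were compared first, since regions called in both replicates were the basis of every later comparison. H3K4me3 had the highest base overlap between replicates (Jaccard index 0.711, against 0.540 for H3K4me1 and 0.522 for H3K27ac), with 89.1% of replicate 1 peaks and 74.5% of replicate 2 peaks found in the other replicate. For H3K27ac, 93.1% of the replicate 2 peaks lay on a replicate 1 peak, whereas only 57.2% of the replicate 1 peaks lay on a replicate 2 peak. H3K4me1 showed the same asymmetry, with 85.6% of replicate 2 peaks and 59.97% of replicate 1 peaks shared. Peaks without a partner were narrow. In H3K27ac replicate 1 their median width was 189 bp against 658 bp for shared peaks. All 6 shares exceeded every circular shift, whose highest value was 4.35% (circular-shift permutation tests, p = 0.002 each, the smallest that 1000 shifts allow). Regions called in both replicates numbered 69490 for H3K4me1, 23935 for H3K4me3 and 19134 for H3K27ac. These are shared parts of peaks, so pieces of 1 wide domain count separately here and, unless stated, in the shares below. Joined over both lists, the regions reached by both replicates numbered 48701, 19731 and 14829.

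The 3 marks overlapped one another far more often than after circular shifts. Of the H3K27ac regions, 75.4% (95% CI 74.8 to 76.0) lay on H3K4me3 and 44.3% (43.6 to 45.0) on H3K4me1. Of the H3K4me3 regions, 45.4% (44.8 to 46.1) held H3K27ac and 48.8% (48.2 to 49.5) touched H3K4me1. Only 11.3% (11.03 to 11.50) of the H3K4me1 regions held H3K27ac, so most H3K4me1 regions had no H3K27ac called in both replicates. Each share was 19.2 to 69.5 times the mean of 1000 circular shifts (permutation tests, p = 0.002 for each). The shares that involve H3K4me1 depended on the replicate. With replicate 1 alone and replicate 2 alone, H3K4me1 lay under 73.3% and 48.1% of H3K27ac regions and under 75.1% and 53.1% of H3K4me3 regions, and H3K27ac lay under 19.6% and 11.9% of H3K4me1 regions, so in replicate 1 more H3K27ac regions lay on H3K4me1 than on H3K4me3 (68.2%).

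BCL6 peaks were set against the marks to ask in which chromatin BCL6 is bound in Tfh cells. BCL6 was found mostly on H3K4me3. Of all BCL6 peaks, 6492 (76.2%, 95% CI 75.3 to 77.1) overlapped H3K4me3, compared with 0.999% on average after circular shifts, a 76.2-fold excess. H3K27ac lay under 4228 peaks (49.6%, 48.5 to 50.7), a 93.4-fold excess over 0.531%. H3K4me1 lay under 1667 peaks (19.6%, 18.7 to 20.4), a 10.0-fold excess over 1.95%. All 3 excesses were above every shift (permutation tests, adjusted p = 0.002 for each). Against local shifts of 20 to 500 kb, which keep the neighbourhood, the excess was 38.4-fold for H3K4me3, 44.0-fold for H3K27ac and 5.07-fold for H3K4me1 (permutation tests, p = 0.002 for each). The H3K4me1 share depended on the replicate, with 36.3% against the replicate 1 list and 20.7% against the replicate 2 list. The H3K27ac share was 64.9% against the replicate 1 list and 51.1% against the replicate 2 list.

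**Figure D1:**
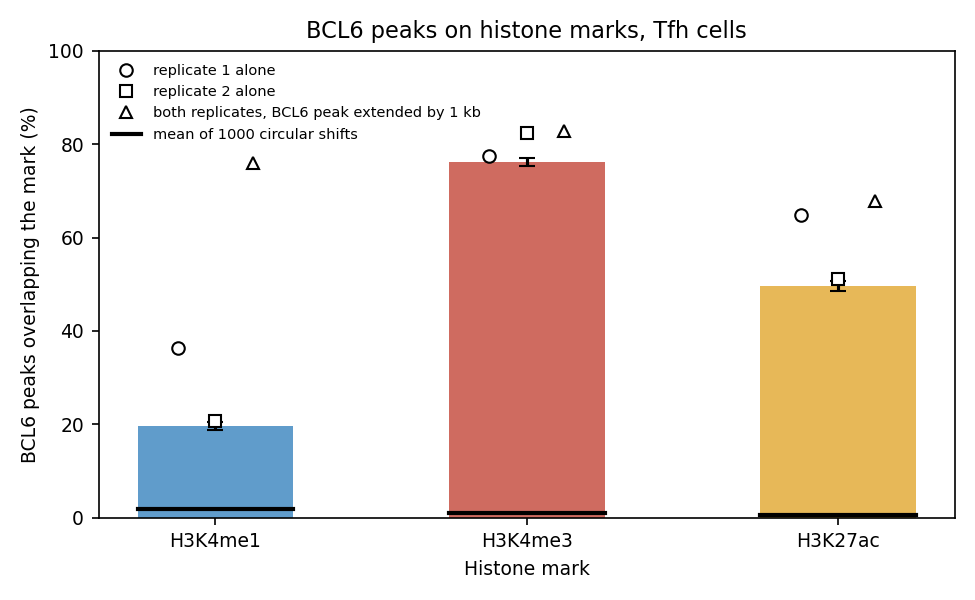
Percent of all BCL6 peaks (vertical axis) that overlap each histone mark (horizontal axis). Bars show regions called in both replicates with exact 95% binomial intervals, symbols show single replicates or BCL6 peaks extended by 1 kb, and black lines show the mean of 1000 circular shifts. The H3K4me3 bar stands at 76.2%, and the H3K4me1 value rises from 19.6% to 76.0% when peaks are extended by 1 kb.

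At BCL6 peaks on H3K4me3, H3K4me1 was called more often beside the peak than under it. H3K4me3 regions without BCL6 were not profiled beside them, so the pattern need not be particular to BCL6 peaks. Extending each BCL6 peak by 1 kb on both sides raised the share of all peaks with H3K4me1 to 76.0%. The mean after circular shifts of the extended peaks was 4.33%. Of the 6492 peaks on H3K4me3, 4948 (76.2%) had H3K4me1 within that distance. At peaks on H3K4me3, the midpoint lay in H3K4me1 in 1.62% of cases and positions 1 kb away in 24.8%, a ratio of 0.0652 (bootstrap 95% interval 0.0538 to 0.0780). At the 951 BCL6 peaks with no H3K4me3 of either replicate within 2 kb, 39.2% of the midpoints lay in H3K4me1, against 46.8% of positions 500 bp away (ratio 0.837, 0.774 to 0.903). With the union of the replicate lists that ratio was 1.08 (1.03 to 1.13). Against positions 1 kb away, the H3K4me1 ratio at these distal peaks was 1.59 (1.43 to 1.76) in both replicates. At peaks on H3K4me3, the ratio against 500 bp was 0.104 (0.0859 to 0.123). H3K27ac at these distal peaks dipped at the midpoint, with 3.15% at the midpoint and 10.99% at 500 bp (ratio 0.287, 0.197 to 0.388). The union gave 9.46% and 21.6% (ratio 0.438, 0.360 to 0.523). At peaks on H3K4me3, the corresponding H3K27ac values were 36.2% and 36.1% (ratio 1.00, 0.971 to 1.04). Closer in, a shallow dip showed there too, since H3K27ac covered 41.3% and 41.4% of positions 300 bp to either side.

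**Figure D2:**
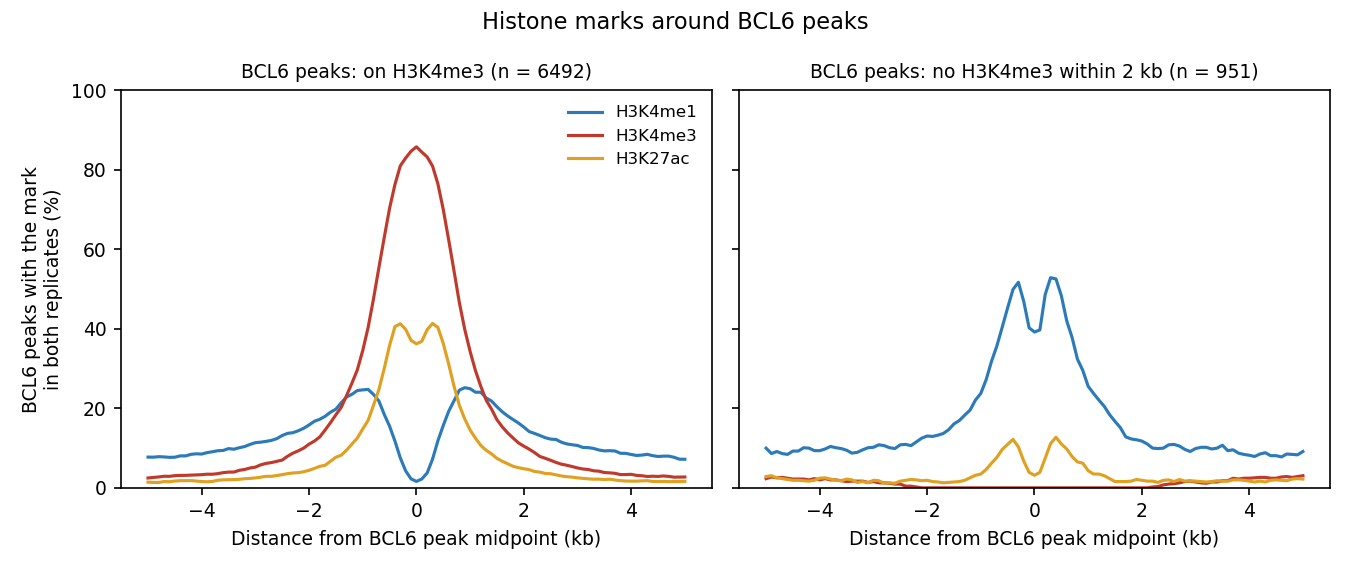
Percent of BCL6 peaks with each mark in both replicates (vertical axis) by distance from the BCL6 midpoint in kb (horizontal axis), for 6492 peaks on H3K4me3 (left) and 951 peaks with no H3K4me3 within 2 kb (right). The left set was chosen for H3K4me3, and H3K4me1 there rises from 1.62% at the midpoint to 24.8% at 1 kb. On the right H3K27ac falls to 3.15% at the midpoint between shoulders.

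Sorted into chromatin classes, BCL6 peaks were predominantly promoter-type. The promoter-type class held 6492 peaks (76.2%), the unacetylated enhancer-type class 804 (9.43%, 8.82 to 10.1) and the active enhancer-type class 249 (2.92%, 2.57 to 3.30). A further 80 peaks (0.939%) carried H3K27ac alone, and 898 (10.5%, 9.89 to 11.2) carried none of the marks in both replicates. Each marked class exceeded every shift and was 76.2, 6.20, 26.0 and 60.2 times the mean of the shifts, in the order given, and unmarked peaks were fewer than the 97.4% average of the shifts (permutation tests, adjusted p = 0.002 for each of the 5 classes). Against the mean of local shifts the excesses were 38.4-fold, 3.19-fold, 11.4-fold and 26.9-fold. Of the promoter-type peaks, 3899 (60.1%) also carried H3K27ac, compared with 329 of 2031 peaks off H3K4me3 (16.2%), an odds ratio of 7.78 (two-sided Fisher's exact p = 3.6e-280, which treats neighbouring peaks as independent). The peaks off H3K4me3 include the 898 that lack H3K27ac by definition. No distance from H3K4me3 was required of them, and only 951 of the 2031 had no H3K4me3 of either replicate within 2 kb. Among all regions, H3K27ac was likewise called in 45.4% of H3K4me3 and 11.3% of H3K4me1 regions, so the contrast need not be particular to BCL6. Of the 898 unmarked peaks, 604 had a mark in 1 replicate, and 294 had none in either. With replicate 1 alone and replicate 2 alone, the active enhancer-type share was 5.71% and 2.30%, the H3K27ac-only share 0.446% and 0.575%, and the unmarked share 5.67% and 6.62%. The overlap rule moved these shares too. By midpoint they were 0.833%, 1.55% and 25.2% in the same order, and with extension by 1 kb 4.79%, 0.0587% and 3.74%.

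BCL6 peak width, the only value a peak carries in these lists, differed between classes. Median widths were 403 bp in the active enhancer-type class, 338 bp in the promoter-type class, 283 bp in the unacetylated enhancer-type class and 198 bp in unmarked peaks. Promoter-type peaks were 55 bp wider than unacetylated enhancer-type peaks (bootstrap 95% interval 41 to 68; permutation test, adjusted p = 1.2e-05) and 140 bp wider than unmarked peaks (127 to 150.5; adjusted p = 1.2e-05). These adjusted values are the smallest that the permutations allow. Active enhancer-type peaks were 65 bp wider than promoter-type peaks (interval of the difference, promoter-type minus active enhancer-type, -110.0 to -35; permutation test, adjusted p = 0.00144). A wide peak touches a mark more easily, so the overlap rule by itself can produce part of the differences between classes. How large that part is was not tested. When the midpoint had to lie inside the mark, promoter-type peaks were 33.5 bp wider than unmarked and 44.5 bp wider than unacetylated enhancer-type peaks (permutation tests, adjusted p = 0.0006 for both), and the difference from active enhancer-type peaks was 71.5 bp in the other direction (adjusted p = 0.087 by permutation test). By the same rule, active enhancer-type peaks were -27 bp against unacetylated enhancer-type and -38 bp against unmarked peaks. Unacetylated enhancer-type peaks were -11 bp against unmarked peaks. None of these differences among the other classes passed the threshold.

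Among H3K4me1 regions that did not overlap H3K4me3, BCL6 was compared between acetylated and unacetylated regions. No distance from H3K4me3 was required, so flanks of H3K4me3 regions are included. A BCL6 peak was present in 393 of 3524 acetylated regions (11.2%, 95% CI 10.1 to 12.2) and in 817 of 52503 unacetylated regions (1.56%, 1.45 to 1.67). Acetylated regions were also wider, with a median of 707 bp against 255 bp. Within width bins the odds ratio was 4.48, and circular shifts gave a median of 1.16 with a central 95% range of 0.534 to 1.99 (permutation test, p = 0.002). The unadjusted odds ratio was 7.94. In absolute numbers, more of the regions with BCL6 were unacetylated (817 against 393). For regions more than 2 kb from H3K4me3 of either replicate, the shares were 11.5% (152 of 1321) and 1.28% (450 of 35112), with a width-stratified odds ratio of 5.47 (permutation test, p = 0.00995, the smallest that 200 shifts allow). With no distance limit, the odds ratio was 2.72 when only BCL6 midpoints were counted (permutation test, p = 0.040).

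**Figure D3:**
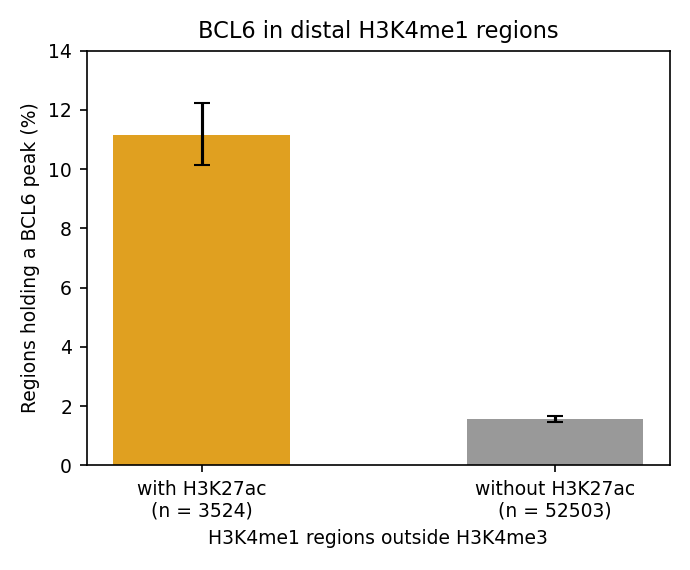
Percent of H3K4me1 regions outside H3K4me3 that hold a BCL6 peak (vertical axis), by presence of H3K27ac in both replicates (horizontal axis). Bars are shares with exact 95% binomial intervals, 11.2% with and 1.56% without H3K27ac.

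The widest BCL6 peaks all lay on H3K4me3. The widest spanned 3732 bp on chromosome 1 (hg18, 59019856 to 59023587) and carried all 3 marks. The next was 3042 bp on chromosome 3 (188938920 to 188941961) and the one after it 2672 bp on chromosome 12 (92487601 to 92490272). The latter was the only one of the 10 widest without H3K27ac, and the nearest H3K27ac region was 101625 bp away. Among active enhancer-type peaks the widest was 1339 bp on chromosome 1 (205023854 to 205025192), 26061 bp from the nearest H3K4me3 region of both replicates, although 1 replicate alone had a 205 bp H3K4me3 call at the peak. Among unacetylated enhancer-type peaks the widest was 1378 bp on chromosome 9 (133593089 to 133594466), with H3K27ac 439 bp away. The second, 1227 bp on chromosome 19 (16342955 to 16344181), had its nearest H3K27ac 46850 bp away. Both also had an H3K4me3 call in 1 replicate alone (348 bp and 247 bp). The widest peak with H3K27ac alone was 942 bp on chromosome 17 (36718205 to 36719146), with H3K4me3 22 bp and H3K4me1 45 bp away. Of the 5 widest unmarked peaks, the one on chromosome 10 (125909439 to 125910227) was the farthest from any mark, with H3K4me3 123234 bp away.

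Broad histone regions differed in their BCL6 content. The H3K4me3 region on chromosome 3 (188937895 to 188946758, 8864 bp), the fourth widest, held 6 BCL6 peaks and H3K27ac. The second widest H3K27ac region, 8680 bp on chromosome 11 (64943989 to 64952668), held 5 BCL6 peaks, and the widest, 10232 bp on the same chromosome (92896503 to 92906734), held 2. No BCL6 peak was called in the third widest, 8457 bp on chromosome 6 (112179359 to 112187815), or in the fifth, 7158 bp on chromosome 4 (35957155 to 35964312). The widest H3K4me3 region and the third widest lay close together on chromosome 10 (41695774 to 41704973 and 41674920 to 41683925) and held neither H3K27ac nor BCL6. Regions prone to artefactual signal were not filtered out here, so these calls may not be true broad H3K4me3 regions. No gene is assigned to these positions, since no annotation of hg18 was used.

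**Figure D4:**
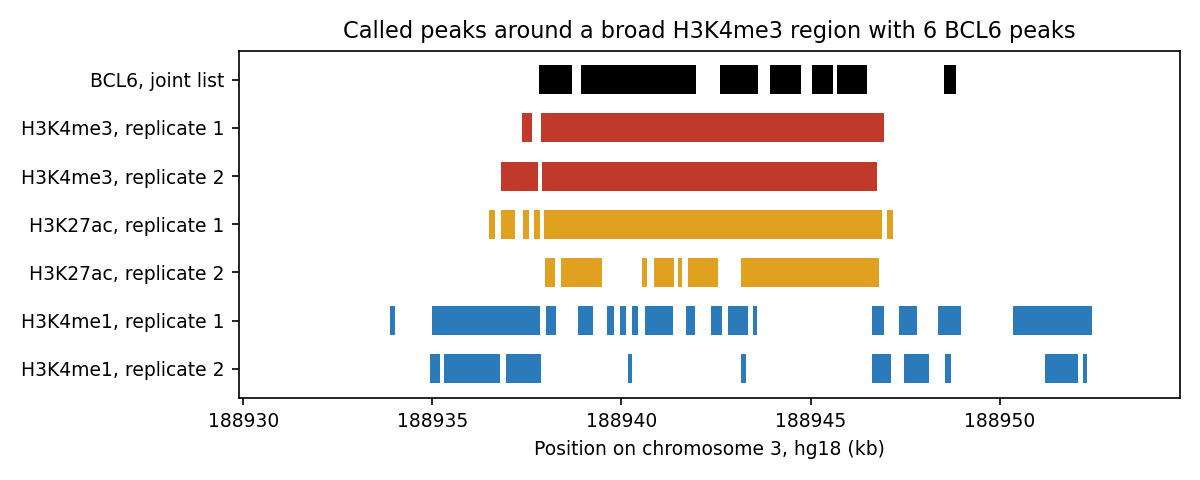
Called peaks of the 7 lists (rows) along chromosome 3 in kb on hg18 (horizontal axis), from 188929895 to 188954758. Filled boxes are peaks drawn to scale, and 6 BCL6 peaks overlap the 8864 bp H3K4me3 region. H3K4me1 is called on both sides of it and, mostly in replicate 1, in short peaks inside it.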

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

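Of 171 alternative values for 26 results, 129 kept their direction and their side of the 0.05 threshold and, for shares of BCL6 peaks and overlaps between marks, stayed within 1.5 times the reported share. This count overstates stability. Random placement and local shifts change the chance level alone, so the shares could not move there. The promoter-type share is the H3K4me3 share by definition and is counted again. The excess of BCL6 on each mark and the higher BCL6 occupancy of acetylated H3K4me1 regions kept their direction and significance under each alternative run. The odds ratio for acetylated regions ranged from 2.72 to 5.84. Requiring the BCL6 midpoint inside the region lowered the shares to 8.59% for H3K4me1 and 29.1% for H3K27ac, and gave 0.833% active enhancer-type, 1.55% H3K27ac-only and 25.2% unmarked peaks. Requiring 50% of the peak to be covered gave 9.07%, 30.4%, 0.974%, 1.84% and 22.1% in the same order. Extension by 1 kb gave 76.0% with H3K4me1, 4.79% active enhancer-type, 0.0587% H3K27ac-only and 3.74% unmarked. Regions of either replicate gave 37.1% with H3K4me1, 0.258% H3K27ac-only and 3.45% unmarked. Unmarked peaks were 4.26% of the widest 50% of BCL6 peaks. With the widest 50% of each histone list they were 19.7%, and H3K27ac-only peaks 2.45%. Without one or the other replicate, the shares ranged from 20.7% to 36.3% for H3K4me1, 2.30% to 5.71% for the active enhancer-type class, 0.446% to 0.575% for H3K27ac alone and 5.67% to 6.62% for unmarked peaks.

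Promoter-type peaks were wider than unmarked peaks in each alternative run, by 33.5 bp (midpoint), 73 bp (50% coverage) and up to 158 bp (without replicate 2), and wider than unacetylated enhancer-type peaks by 42 to 88.5 bp. Promoter-type minus active enhancer-type, -65 bp as reported, was -1 bp with regions of either replicate, 71.5 bp by midpoint, 39 bp by 50% coverage and 1.5 bp with extension (permutation tests, adjusted p between 0.087 and 0.96), and -56.5 to 3 bp without one or the other replicate. It passed the threshold without replicate 1 (permutation test, adjusted p = 0.0107) and as the mean of log2 width (-0.171; permutation test, adjusted p = 0.0035). By midpoint, active enhancer-type peaks were -27 bp against unacetylated enhancer-type and -38 bp against unmarked peaks, and unacetylated enhancer-type were -11 bp against unmarked peaks. With 50% of the peak covered, active enhancer-type peaks were 3 bp wider than unacetylated enhancer-type and 34 bp wider than unmarked peaks. None of these midpoint and coverage values passed the threshold. The cause was not tested. With a replicate block, comparing marks within each replicate number, the shares were 49.5% of H3K4me3 regions with H3K27ac, 64.1% of H3K4me3 with H3K4me1, 15.7% of H3K4me1 with H3K27ac, 73.2% of H3K27ac with H3K4me3 and 60.7% of H3K27ac with H3K4me1, and no call changed. Between marks, either replicate gave 76.1% of H3K4me3 and 75.5% of H3K27ac regions with H3K4me1 and 19.3% of H3K4me1 with H3K27ac. Without one or the other replicate these ranged from 53.1% to 75.1%, 48.1% to 73.3% and 11.9% to 19.6%. Alternatives by peak score, the second score column and the gene-list tests were not run, for want of scores and of an hg18 annotation. The BCL6 replicates could not be left out in turn because they share 1 list. Without depth, a missing peak does not show a missing mark.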

Other observations

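H3K4me3 regions differed widely in how often they held BCL6. Of 19731 H3K4me3 regions reached by both replicates and measured over their joint extent, 6045 (30.6%) held a BCL6 peak. The share rose with width, from 10.8% in the narrowest of 5 width bins (109 to 568 bp) to 58.0% in the widest (1803 to 21983 bp), as a wider region also does by chance. Acetylated H3K4me3 regions held BCL6 in 44.7% of cases (4462 of 9991) and unacetylated regions in 16.3% (1583 of 9740). The odds ratio within width bins was 2.66, against a median of 1.05 and an upper limit of 1.74 in 1000 circular shifts (permutation test, p = 0.002). In every bin the acetylated regions had the higher share, 19.5% against 8.02% in the narrowest and 63.6% against 37.5% in the widest.

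BCL6 peaks also came in runs. Of 8267 autosomal peaks, 3197 (38.7%) had another BCL6 peak less than 10 kb away, and 93 runs held 4 or more peaks. The longest held 8 peaks on chromosome 11 (64940461 to 64949105), followed by 7 on chromosome 2 (218968944 to 218980277) and 7 on chromosome 3 (188937808 to 188948852). In the chromosome 3 run, 1 peak ended at 188945591 and the next began at 188945697, so the peaks of a run need not be separate binding sites. No share expected by chance was set beside these values. These runs were chosen after their values were seen.

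The occupancy and run analyses above were chosen after the lists had been examined. The tests below were chosen after the patterns had been seen, with their bounds set before the test values were, apart from the H3K27ac values at 1 kb, which were chosen after the 500 bp result, so each explanation stays a hypothesis. H3K4me1 was called less often at BCL6 midpoints than 1 kb away. Gaps made by intersecting 2 lists are argued against, because the union of the lists gave a ratio of 0.452 (0.433 to 0.472). H3K4me3 taking the place of H3K4me1 met the bound set for it. BCL6 peaks with no H3K4me3 within 2 kb showed the opposite ratio at that distance, 1.59 (1.43 to 1.76). Against 500 bp the same peaks gave 0.837 (0.774 to 0.903) in both replicates and 1.08 (1.03 to 1.13) in the union. In both replicates H3K4me1 covered 39.2% of their midpoints, and 51.7% and 52.9% of positions 300 bp to either side. The ratio at 1 kb cannot show such a narrower dip, so it does not decide on this explanation. Few histones at the bound site cannot be told apart from these explanations, although H3K27ac at those distal peaks met the bound set for it 500 bp away (ratio 0.287, 0.197 to 0.388). At 1 kb, the distance of the pattern, that ratio was 0.811 (0.560 to 1.19) and 1.03 in the union. Over all BCL6 peaks H3K27ac was called more often at the midpoint than 1 kb away (2.19, 2.09 to 2.28). H3K27ac regions had a median width of 330 bp, so these values at 1 kb cannot show or exclude a narrower gap. Over all BCL6 peaks, H3K27ac covered 29.1% of midpoints, and 35.3% and 35.5% of positions 300 bp to either side.

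Most BCL6 peaks lay on H3K4me3. Gene-dense neighbourhoods and assembly gaps in the chance model are argued against as the whole cause by the 38.4-fold excess over local shifts. Of the BCL6 peaks on H3K4me3, 84.7% (83.8 to 85.5) had an H3K4me3 region of 1 kb or more. Most of this overlap was therefore not on H3K4me3 regions narrower than 1 kb, which narrow H3K4me3 at distal elements would have required. Wide regions also catch more peaks by chance, and no share expected from width was set beside this value. Whether the regions are distal was not measured, so distal elements with wide H3K4me3 are not excluded. Precipitation of every open promoter alike cannot be told apart from specific binding: 63.6% (61.8 to 65.2) of the widest acetylated H3K4me3 regions held a BCL6 peak, between the bounds of under 50% and over 90% set for the test, and no control immunoprecipitation was analysed here.

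The H3K27ac list of replicate 2 was almost contained in that of replicate 1. Of the 11498 unshared peaks of replicate 1, 90.7% lay on H3K4me1 or H3K4me3 of both replicates, 37.3 times the mean of 1000 shifts. This argues against false peaks scattered without regard to these marks as the source of most unshared peaks. Background signal raised at marked regions would give the same overlap, so false peaks of that kind are not excluded. Unshared peaks of replicate 1 had 0.287 times the median width of shared ones (0.280 to 0.296), which met the bound for lower depth or a stricter call in replicate 2. However, unshared peaks were narrower in all 6 histone lists, including H3K27ac replicate 2 (140 bp against 362 bp). The widths therefore cannot decide on that explanation. A difference in acetylation between the cells of the replicates was not tested and stays open.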
